A study of Xenopus laevis with 16 samples.

How the data were processed

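Total RNA from pooled animal caps of Xenopus laevis was measured on 16 single-colour Affymetrix Xenopus arrays, 4 in each of 4 groups: uninjected or foxD5-injected caps, each without or with 200 ng/ml Noggin. The deposited values are intensity, a signal on a linear scale with 1 value per probe set. They are positive, and the mean without the lowest and highest 2% was 150.02 on every array, so the authors' values share a common scale. The sources used here do not name the software that made them. The labels give a source tissue that contradicts the descriptions of the samples, and the descriptions were followed. The labels do not state that the numbered samples are independent clutches, so p values measure the spread between these samples.

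Sample groups, comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The values were transformed as log2(value + 16). Array medians then ranged from 5.79 to 6.35, wider than the 0.2 allowed for leaving values as deposited, so arrays were quantile normalised. Of 15611 probe sets, 120 Affymetrix controls were left out and 15491 tested, with no filter on low signal. The platform annotation gave 1 gene symbol for 9304 probe sets, several for 195 and none for 5992. By Entrez identifier 9227 symbols were found among current RefSeq genes, which renamed 2, and 7531 distinct symbols remained. The suffixes .L and .S mark the homeologs of this allotetraploid species and were counted as separate genes.

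The comparisons used R 4.3.3 and limma 3.58.1 with empirical Bayes moderation, tests were two-sided, and p values were adjusted by Benjamini and Hochberg over all probe sets, with a threshold of 0.05. Each control is labelled as siblings of a numbered injected sample. Of the injected samples, 1 in each culture has no number and was taken as number 1, the only number left. The 3 effects of foxD5 (without Noggin, in Noggin, and their mean over 8 pairs) and the difference of its effects were fitted on all 16 arrays with sibling pair as a fixed block (6 residual degrees of freedom before moderation). Without the sibling block the mean effect of foxD5 called 67 probe sets in place of 213. As a check of the pairing, deviations from group means correlated between siblings at 0.203 to 0.670 in 7 pairs and at -0.115 in pair 1 lacking Noggin, and 13 of 16 arrays were closest to their own sibling. The labels do not link numbers across cultures, so the 2 comparisons with and without Noggin were fitted on group means with sibling pair as a random block (correlation 0.364, 12 residual degrees of freedom), and clutch is confounded with Noggin there.

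Of 19 gene lists fixed in advance, 18 with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with 1 probe set per symbol, that with the highest mean. The list of the injected gene held 2 and was not tested. The older names tcf3, gem and esr1 were removed from the lists once the annotation was read, because these symbols now name other genes. Camera was repeated with an estimated correlation. An exact sign-flip test of each list's mean over the 8 sibling pairs, with p values adjusted over 18 lists, was added after the data were seen. It takes the 8 pairs as independent, which the labels do not state. Also added then were the correlation of the Noggin effects over other ways to part the 8 sibling pairs, the exchange of siblings for the correlation of foxD5 and Noggin effects, the list tests with a keratin score, and the lists for low oxygen and glycolysis and for p53 targets.

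The named genes were those of the injected gene and of 11 other neural fate transcription factors, and the 8 largest rises and 8 largest falls past the threshold with 1 symbol that moved the same way in every pair. The same-way condition applied to the paired comparisons only. Where fewer than 3 genes passed in a direction, the 3 with the smallest p were named. From 2 to 4 members with the smallest p were added for each list that passed or held at least 3 changed members. Genes named outside this rule are said to be so.

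Alternatives were no sibling block or a random one, the replicate number as a block across cultures, values as deposited or centred on the median, a pseudocount of 1 or 64, only the probe sets with a mean above the median, an intensity trend, array weights, only the 8 arrays of a comparison, the median over a gene's probe sets in the list tests, and leaving out each pair or array. Leaving out pairs 1 and 2 lacking Noggin, or pairs 1 and 4 lacking Noggin and pair 2 in Noggin, was added after the data were seen. The fits were tested on simulated data with 200 changed of 15491 probe sets in 5 simulations. At a log2 change of 1.0 the fits recovered 72.8% for foxD5 without Noggin, 64.5% for foxD5 in Noggin and 92.8% for both cultures. For Noggin they recovered 54.3% in uninjected caps and 54.6% in injected caps. The values were drawn on the normalised log2 scale, with independent genes and the same correlation in every sibling pair. Normalisation and the compression of low signals by the pseudocount were thus not tested, and recovery on the real arrays may be lower. A difference between the foxD5 effects was not simulated. Figures were drawn with matplotlib 3.10.9. Coordinates were not used.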

Results

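Gene expression was measured in explanted animal caps of Xenopus laevis, the ectoderm of the blastula, which forms epidermis when cultured alone. Each of 16 samples of total RNA was hybridised to its own single-colour Affymetrix Xenopus array. The samples form 4 groups with 4 arrays each. Caps came from uninjected embryos or from embryos that received 100 pg of foxD5 mRNA in each cell at the 2-cell stage, and each kind was cultured with or without 200 ng/ml Noggin, a secreted antagonist of BMP ligands. FoxD5 is a forkhead transcription factor of the early neural ectoderm whose gene now carries the symbol foxd4l1. The labels tie every injected sample to uninjected siblings of the same number, which gives 4 pairs without Noggin and 4 other pairs in Noggin. No sample received another mRNA. An effect of foxD5 therefore means foxD5-injected against uninjected siblings, and injection as such cannot be told apart from it. Samples held 45 to 171 caps, with 45 in control 1 and 171 in its injected sibling. Caps were harvested at gastrula to early neurula stages, and in Noggin the labelled stage was later in the injected caps in 3 of 4 pairs and equal in 1, while controls without Noggin carry no stage. The number of arrays limits the precision of every value, and an array has no read depth. Of 15491 probe sets tested, 4413 (28.5%) had a mean signal under 16.

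The first comparison asked what foxD5 changed in caps without added Noggin, under a series title that speaks of stabilising neural fate. Of 38 measured epidermis genes 5 fell. The deposited signal of foxi1.L, a forkhead gene of ionocyte progenitors, was 16.8 ± 8.98 in injected caps and 114 ± 38.9 in controls (mean ± SD, n = 4 arrays each). That of bmp7.2.L, a BMP ligand gene, was 252 ± 46.6 against 856 ± 292. Rises included fgf8.L, which encodes a fibroblast growth factor, at 465 ± 152 against 111 ± 53.8, and vegt.L, a T-box gene of endoderm and mesoderm, at 597 ± 114 against 176 ± 91.7. In the limma fit with sibling pair as a block, 37 probe sets changed, 18 higher and 19 lower, and 1581 had an unadjusted p under 0.05.

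Of 38 measured epidermis genes without Noggin, 5 fell, 0 rose and 33 did not pass. Adjusted over the list alone, 14 fell. The members that fell were foxi1.L (log2 change -1.94 ± 0.28 SE, limma adjusted p = 0.0164, lower in 4 of 4 pairs), tfap2a.L, klf17.L, foxi4.2.L and grhl3.L. The changes of the last 4 were -1.44 ± 0.24, -1.38 ± 0.19, -1.32 ± 0.20 and -1.19 ± 0.17. TFAP2A, KLF17 and GRHL3 are transcription factors of the outer or non-neural ectoderm. The list as a whole was lower than other genes in limma's camera test (adjusted p = 1.7e-11 with the preset correlation, adjusted p = 0.507 with an estimated correlation). The list's mean differed widely between pairs, from -1.55 in pair 1 to 0.02 in pair 3. The 14 keratin genes, which are among its 38 members and so move its mean, were at -1.51 in pair 1 and 0.14 in pair 3.

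Of 39 measured genes of the BMP pathway and its direct targets, 2 fell without Noggin, bmp7.2.L (-1.70 ± 0.21) and msx1.L (-1.55 ± 0.27), and 37 did not pass. Adjusted over the list alone, 6 fell. The values of szl.L, which encodes the BMP feedback inhibitor Sizzled, and its homeolog szl.S were -1.37 ± 0.27 (adjusted p = 0.0856) and -1.14 ± 0.29 (adjusted p = 0.198). The list was lower by camera (adjusted p = 0.0123, and adjusted p = 0.636 with an estimated correlation). That call ended without pair 1 (adjusted p = 0.609) or without pair 4 (adjusted p = 0.235), and without pairs 1 and 2 together (adjusted p = 0.149).

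The other large falls without Noggin were menf.1.L (-2.02 ± 0.35), cnn2.S, which encodes a calponin (-1.86 ± 0.20), hal.1.L, which encodes histidine ammonia-lyase (-1.69 ± 0.18), and the fibroblast growth factor receptor gene fgfr4.S (-1.57 ± 0.20). The rises were led by fgf8.L (1.99 ± 0.27), foxb1.S (1.99 ± 0.34), pnp.L, a purine salvage enzyme gene (1.82 ± 0.30), vegt.L (1.81 ± 0.27) and nradd.L (1.77 ± 0.20). Further rises were those of hmox1.L, which encodes heme oxygenase (1.64 ± 0.22), ambp.L (1.58 ± 0.21) and slc43a2.L, an amino acid transporter gene (1.504 ± 0.190). All 37 probe sets moved the same way in 4 of 4 pairs. Without pair 1, 2, 3 or 4 the count was 26, 16, 29 or 7, and nradd.L, hmox1.L, cnn2.S and hal.1.L passed in each of these 4 fits. Without the sibling block it was 1.

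The second comparison asked what foxD5 changed in caps already exposed to Noggin. Injected caps in Noggin had higher mmp14.L, which encodes a membrane matrix metalloproteinase (318 ± 173 against 50.9 ± 21.1, n = 4 arrays each), and higher fgf8.L (571 ± 57.7 against 175 ± 96.1). They had lower hal.1.L (211 ± 132 against 775 ± 559) and foxi1.L (9.86 ± 10.03 against 80.3 ± 67.0). In the limma fit 49 probe sets changed, 37 higher and 12 lower, and 1141 had an unadjusted p under 0.05. The log2 rises were mmp14.L 2.08 ± 0.27 (SE), dhcr7.S, a cholesterol synthesis gene, 1.78 ± 0.28, nradd.L 1.73 ± 0.20, fgf8.L 1.71 ± 0.27, hmox1.L 1.69 ± 0.22, hes7.2.L, a hairy/enhancer-of-split repressor gene, 1.68 ± 0.23, alpl.L 1.68 ± 0.31 and vegt.L 1.64 ± 0.27. The falls were hal.1.L -1.74 ± 0.18, foxi1.L -1.66 ± 0.28, bmp7.2.L -1.36 ± 0.21, foxi4.2.L -1.15 ± 0.20, fgfr4.S -1.14 ± 0.20, hs3st1.L -1.14 ± 0.16 and klf2.S -1.09 ± 0.18. All 49 probe sets moved the same way in 4 of 4 pairs.

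In Noggin, 2 of 38 epidermis genes fell (foxi1.L and foxi4.2.L) and 36 did not pass, with 6 lower adjusted over the list alone. The values of tfap2a.L (-1.23 ± 0.24, adjusted p = 0.0666) and grhl3.L (-0.71 ± 0.17, adjusted p = 0.146) did not pass. Of 39 BMP genes, 1 fell (bmp7.2.L) and 38 did not pass, with 4 lower adjusted over the list alone. The values of szl.L, szl.S and msx1.L were -1.33 ± 0.27, -1.23 ± 0.29 and -1.03 ± 0.27 (adjusted p = 0.0808, 0.156 and 0.251). By limma's camera the epidermis list was lower (adjusted p = 6.1e-05, and adjusted p = 0.533 with an estimated correlation), as was the BMP list (adjusted p = 0.00124, and adjusted p = 0.533 with an estimated correlation). Without pair 1, 2, 3 or 4 in Noggin the count of 49 became 6, 5, 18 or 7, and nradd.L and hal.1.L passed in each. Without the sibling block it was 3.

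Of the probe sets that passed, 16 did so in both cultures, 10 higher in both and 6 lower in both. The cultures share no array but were fitted with a common residual variance, and with the 8 arrays of each culture alone 0 were shared, as 0 then passed without Noggin and 37 in Noggin. The named ones were fgf8.L, vegt.L, nradd.L, hmox1.L, ambp.L, slc43a2.L and sesn1.L, which rose, and foxi1.L, foxi4.2.L, bmp7.2.L, hal.1.L and fgfr4.S, which fell. All 70 probe sets that passed in either culture had the same sign in the other, with a correlation across them of 0.920. These 70 were chosen for passing. Across all probe sets 56.4% had the same sign, Pearson's r was 0.367 and Spearman's rho 0.222, where probe sets are not independent replicates. Leaving out 1 pair gave 3 to 18 shared probe sets, with fewer than 11 without pair 4 lacking Noggin (5) or pair 1, 2, 3 or 4 in Noggin (4, 3, 6 and 4).

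**Figure D1:**
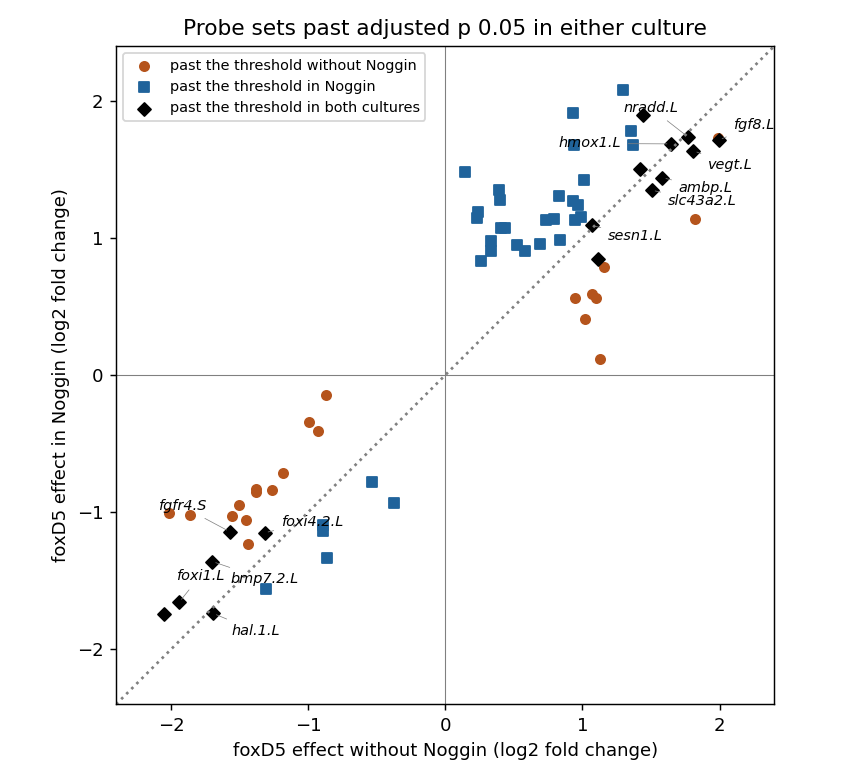
Log2 fold change of foxD5-injected over uninjected sibling caps without Noggin (horizontal axis) and in Noggin (vertical axis), for the 70 probe sets past the adjusted p of 0.05 in either culture, with those that passed in both as black diamonds and the dotted line marking equal effects. All 70 points lie in the lower left or the upper right of the plot.

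Averaged over the 8 sibling pairs, 213 probe sets differed between foxD5-injected and uninjected caps by limma, 137 higher and 76 lower. Of these, 174 moved the same way in 8 of 8 pairs and 70 changed over 2-fold. The number at an unadjusted p under 0.05 was 1792. A mean over both cultures can also pass on the effect in 1 of them, as for ptgds-b, named after its values were seen, at 0.14 without Noggin and 1.48 in Noggin. All 37 probe sets called without Noggin and all 49 called in Noggin were among the 213. The log2 falls were foxi1.L -1.80 ± 0.20 (SE, limma adjusted p = 9.1e-04), hal.1.L -1.72 ± 0.12, bmp7.2.L -1.53 ± 0.15, cnn2.S -1.44 ± 0.14, fgfr4.S -1.36 ± 0.14, szl.L -1.35 ± 0.19, tfap2a.L -1.33 ± 0.17 and msx1.L -1.29 ± 0.19. The log2 rises were foxb1.S 1.86 ± 0.24, fgf8.L 1.85 ± 0.19 (adjusted p = 6.8e-04), hes7.1.L 1.83 ± 0.36, nradd.L 1.75 ± 0.14, vegt.L 1.72 ± 0.19, mmp14.L 1.69 ± 0.19, hmox1.L 1.66 ± 0.16 and dhcr7.S 1.57 ± 0.20. Each of these 16 genes moved the same way in 8 of 8 pairs, which was a condition for naming them and not a result. It left out egr1.L (2.26 ± 0.42, higher in 7 of 8 pairs) and menf.1.L (-1.51 ± 0.25, lower in 7 of 8).

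**Figure D2:**
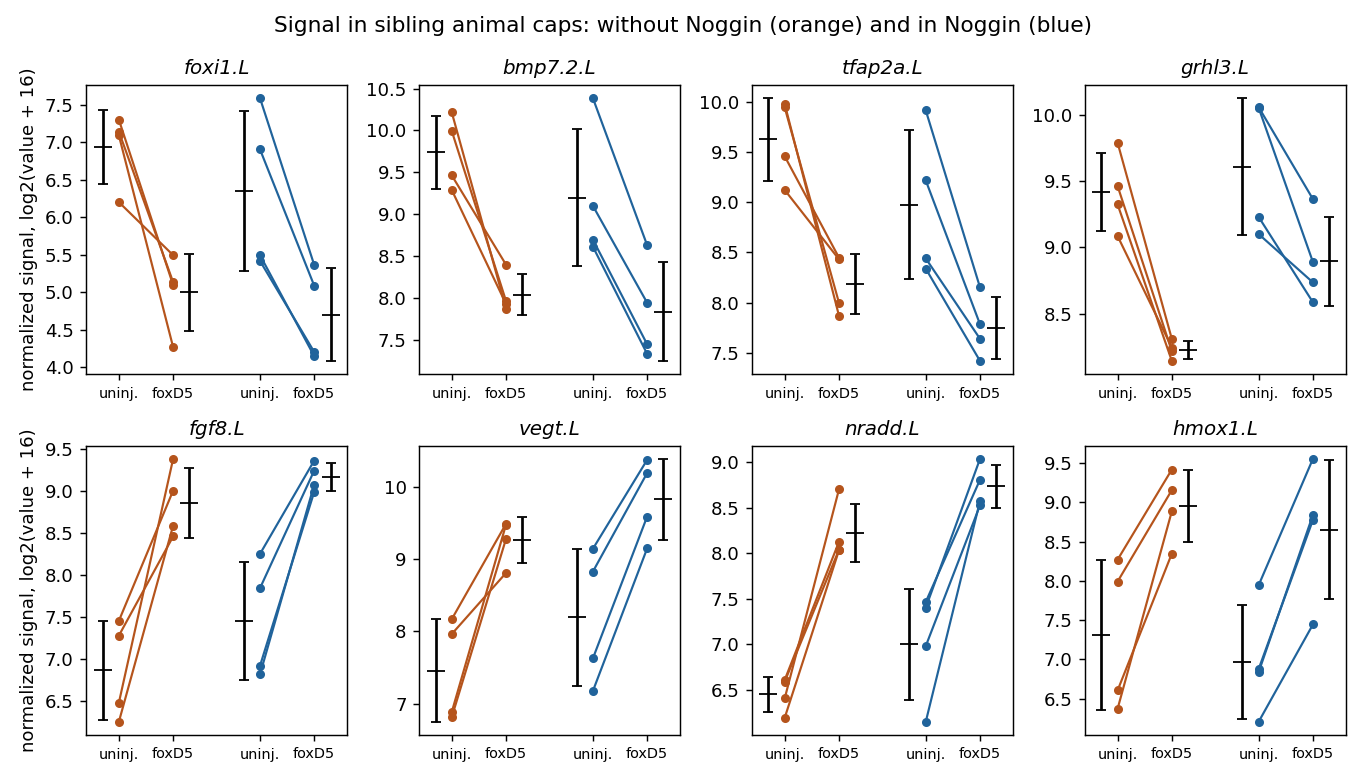
Normalised signal, log2(value + 16), of 4 genes that fell (top) and 4 that rose (bottom), in uninjected and foxD5-injected caps, with siblings joined by lines, orange without Noggin and blue in Noggin, and bars giving the mean ± SD of 4 arrays. Each gene moved the same way in 8 of 8 pairs, which for all but grhl3.L was a condition for naming it among the largest changes.

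Among 38 epidermis genes over both cultures, 6 fell and 32 did not pass, with 14 lower adjusted over the list alone. They were foxi1.L, tfap2a.L, foxi4.2.L (-1.23 ± 0.14), klf17.L (-1.11 ± 0.14), grhl3.L (-0.95 ± 0.12) and gata2.L (-1.28 ± 0.20), the last named after its values were seen. The list was lower by camera (adjusted p = 1.1e-10, and adjusted p = 0.291 with an estimated correlation). Its mean over the sibling pairs was -0.51 ± 0.51 (SD), lower in 7 of 8 pairs, with an exact sign-flip p = 0.0156 (adjusted p = 0.0562, a test added after the data were seen). The 14 keratin genes, themselves members of this list, differed by -0.35 ± 0.55 (SD), lower in 6 of 8 pairs. Of these, krt70.S fell in a probe set other than its brightest (-0.59 ± 0.13 SE, limma adjusted p = 0.0431, lower in 8 of 8 pairs). It was named after its values were seen. Among 39 BMP genes 5 fell and 34 did not pass, with 10 lower and 1 higher adjusted over the list alone. The 5 were bmp7.2.L, szl.L, msx1.L, szl.S (-1.18 ± 0.20) and, named after its values were seen, smad7.L (-0.72 ± 0.14). The BMP list was lower by camera (adjusted p = 6.4e-04, and adjusted p = 0.452 with an estimated correlation), a call that ended without pair 1 lacking Noggin (adjusted p = 0.0786). In the exact sign-flip test its mean of -0.24 ± 0.23 was lower in 6 of 8 pairs (adjusted p = 0.0938). Neither list passed camera with pairs 1 and 4 lacking Noggin and pair 2 in Noggin left out (adjusted p = 0.0537 and 0.454), the 3 pairs with the largest keratin differences.

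Of 14 genes of ciliated cells and ionocytes, 0 passed by limma, also adjusted over the list alone, while 2 had an unadjusted p under 0.05 and 13 of 14 log2 changes were negative. The changes with the smallest p were ca12.L -0.39 ± 0.15, ubp1.L -0.53 ± 0.21, notch1.S 0.21 ± 0.10 and ccno.L -0.35 ± 0.17 (adjusted p = 0.317, 0.358, 0.462 and 0.463). The list was lower by camera (adjusted p = 0.0267, and adjusted p = 0.291 with an estimated correlation). Its mean was -0.18 ± 0.10 (SD), lower in 8 of 8 pairs, with an exact sign-flip p = 0.0078, the smallest that 8 pairs can give (adjusted p = 0.0469). The camera call ended without pair 1 lacking Noggin (adjusted p = 0.0782) or pair 2 in Noggin (adjusted p = 0.0570), with a pseudocount of 1 or 64 (adjusted p = 0.0669 and 0.0557), with the probe sets of a mean above the median alone (adjusted p = 0.191), and without pairs 1 and 4 lacking Noggin and pair 2 in Noggin (adjusted p = 0.179).

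Genes of the FGF pathway moved both ways. Of 20 measured, 4 rose, 2 fell and 14 did not pass, and 7 were higher and 3 lower adjusted over the list alone. The ligand gene fgf8.L and the phosphatase gene dusp1.S (0.77 ± 0.14) rose, as did, named after their values were seen, egr1.L (2.26 ± 0.42, higher in 7 of 8 pairs), an immediate early gene, and spry2.S (0.72 ± 0.14), a feedback inhibitor gene. The receptor genes fgfr4.S and fgfr4.L (-0.99 ± 0.14) fell. The list was higher by camera (adjusted p = 0.0297, and adjusted p = 0.291 with an estimated correlation), and its mean of 0.25 ± 0.12 (SD) was higher in 8 of 8 pairs (exact sign-flip adjusted p = 0.0469). The camera call ended when pair 1 or 3 lacking Noggin (adjusted p = 0.0802 and 0.0733) or pair 1 or 2 in Noggin (adjusted p = 0.114 and 0.0537) was left out. It also ended with a pseudocount of 1 or 64 (adjusted p = 0.0729 and 0.0557), with the probe sets of a mean above the median alone (adjusted p = 0.249), with the median over a gene's probe sets (adjusted p = 0.0689), and without pairs 1 and 4 lacking Noggin and pair 2 in Noggin (adjusted p = 0.136).

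Of 38 mesoderm genes, 4 rose, 1 fell and 33 did not pass over both cultures, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.161). The list's mean of 0.15 ± 0.13 (SD) was higher in 7 of 8 pairs (exact sign-flip p = 0.0156, adjusted p = 0.0562). The median of the 38 changes was only 0.035 (SD 0.50 across genes), so this mean leans on the few large rises. The genes that passed were fgf8.L, foxb1.S, tbxt.S, which encodes Brachyury (0.65 ± 0.13), and fgf20.L (0.73 ± 0.15, named after its values were seen), which rose, and foxf1.L, a gene of ventral and lateral mesoderm (-0.77 ± 0.12), which fell. The signals of tbxt.S were low, at 27.6 ± 23.2 and 21.8 ± 4.05 in injected caps without and in Noggin, against 8.09 ± 6.84 and 9.76 ± 4.72. Of 22 Notch pathway genes 2 rose, hes7.1.L and hes2.L (0.71 ± 0.12), and 20 did not pass, with 4 higher adjusted over the list alone (camera adjusted p = 0.0925). Among the 20, hes7.2.L rose in a probe set other than its brightest by 1.31 ± 0.17 (limma adjusted p = 0.00203, higher in 8 of 8 pairs). The Notch list's mean of 0.17 ± 0.09 (SD) was higher in 8 of 8 pairs (exact sign-flip adjusted p = 0.0469).

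The neural fate transcription factors, among which foxD5 is counted, mostly did not pass. Of 13 measured genes of this list, 0 rose, 1 fell and 12 did not pass over both cultures by limma, with 2 lower adjusted over the list alone (camera adjusted p = 0.800). The one that fell was irx1.L (-0.71 ± 0.11, adjusted p = 0.00797, lower in 8 of 8 pairs). The value of zic1.S was -0.67 ± 0.16 (adjusted p = 0.0802). For sox2.L the brighter of its probe sets gave 0.35 ± 0.19 (adjusted p = 0.501), and the other rose by 0.85 ± 0.18 (adjusted p = 0.0408, higher in 8 of 8 pairs). The remaining changes were gmnn.L 0.30 ± 0.17, gmnn.S -0.25 ± 0.14, sox11.S 0.21 ± 0.13, zic2.S 0.19 ± 0.14, irx3.L 0.16 ± 0.14, irx2.L -0.15 ± 0.11, sox3.S 0.08 ± 0.15, zic2.L -0.04 ± 0.17 and sox15.L 0.02 ± 0.12. That of sox3.L, at a signal near 10, was also close to 0 (adjusted p = 0.999). Signals of sox11.S and sox3.S were already high in controls, at 2111 ± 473 and 925 ± 247 (n = 4).

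Neither probe set named for the injected gene passed. The changes were 0.44 ± 0.29 for foxd4l1.1.S (adjusted p = 0.579, higher in 5 of 8 pairs) and -0.19 ± 0.12 for foxd4l1.2.L (adjusted p = 0.575). The signal of foxd4l1.2.L lay under 16 in all 4 group means. The labels do not say which part of the gene the injected mRNA held.

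**Figure D3:**
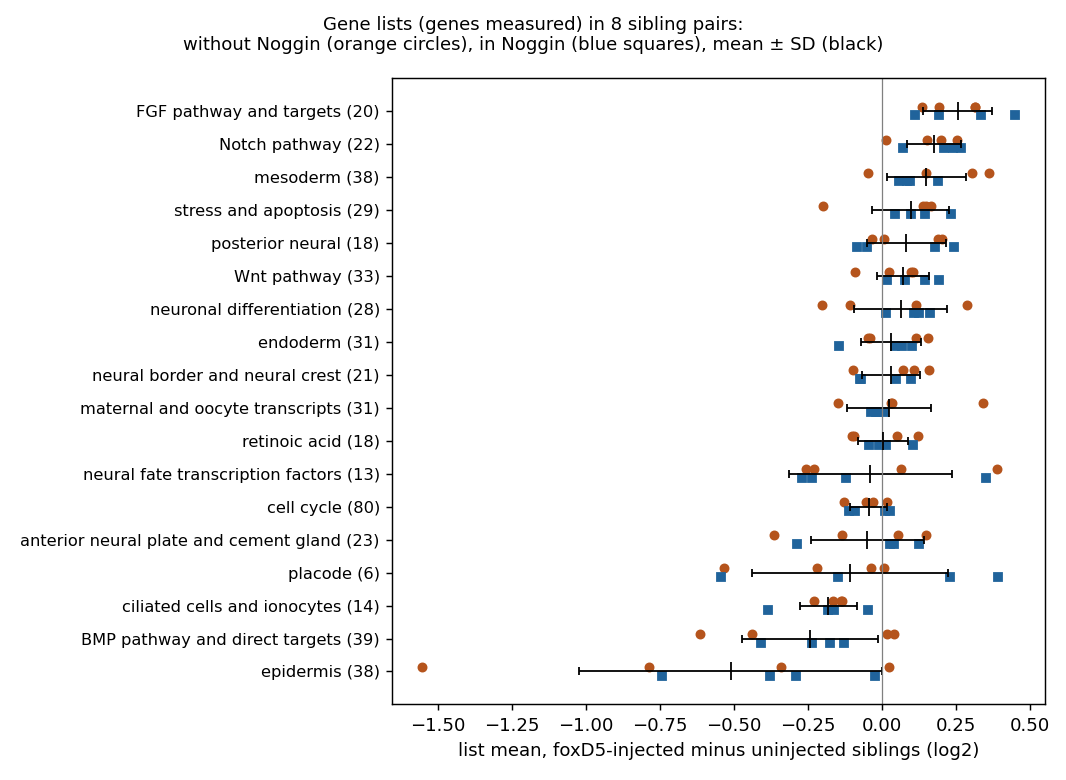
Mean log2 difference of each of 18 gene lists between injected and uninjected siblings, with 1 point per sibling pair, orange circles for 4 pairs without Noggin and blue squares for 4 pairs in Noggin, and black bars for the mean ± SD of 8 pairs. The FGF and Notch lists were higher, and the list of ciliated cells and ionocytes lower, in 8 of 8 pairs.

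The other 11 lists did not pass by camera over both cultures (adjusted p from 0.185 to 0.990). Of 28 neuronal differentiation genes 2 rose, elavl3.L (0.84 ± 0.17) and tubb2b.S (0.76 ± 0.16), and of 31 endoderm genes 2 rose, vegt.L and foxa4.L (0.76 ± 0.11). Of 29 stress and apoptosis genes 2 rose, hmox1.L and sesn1.L (1.08 ± 0.12), and of 31 maternal and oocyte transcripts 2 rose, vegt.L and wnt11b.L (0.96 ± 0.18), the latter also the only one of 33 Wnt genes. Of 18 posterior neural genes 1 rose, cdx1.S (1.07 ± 0.24), and of 80 cell cycle genes 1 rose, ccnd1.L (0.67 ± 0.13). These genes, except hmox1.L and vegt.L, were named after their values were seen. No gene passed by limma among 23 of the anterior neural plate and cement gland, 21 of the neural border and crest, 6 of the placodes and 18 of retinoic acid signalling. At an unadjusted p under 0.05 there were 2, 4, 1 and 3 of these.

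The count over both cultures moved with single pairs. Leaving out pair 1 lacking Noggin raised it from 213 to 393, while leaving out pair 4 lacking Noggin, or pair 1, 2 or 4 in Noggin, lowered it to 92, 108, 115 or 107. Without the sibling block it was 67, all among the 213, and with 1 pair left out in turn the call of tbxt.S ended in 6 of 8 fits, dusp1.S in 4, hes7.1.L in 3 and szl.S in 1.

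Whether foxD5 acted differently in Noggin was tested as the difference of its effects. No probe set passed by limma (0 of 15491, with 765 at an unadjusted p under 0.05). The median SE of this difference was 0.259, against 0.129 for the mean effect over both cultures. Recovery of a true difference was not simulated, so the lack of calls does not show that foxD5 acted alike in both cultures. The genes with the smallest p were ptgds-b, 1.34 ± 0.25 more positive in Noggin, baz2b.S, 1.097 ± 0.255, and inhbb.L, 0.95 ± 0.23, and in the other direction tal1.S, -1.06 ± 0.24, src.S, -1.03 ± 0.26, and pdk1.S, -0.84 ± 0.21 (adjusted p = 0.926 for each). The differences for irx1.L and zic1.S were 0.21 ± 0.22 and -0.25 ± 0.33, and those of the other neural fate genes ranged from -0.54 ± 0.28 (gmnn.S) to 0.48 ± 0.28 (irx3.L). The epidermis list was more positive in Noggin by camera, with 31 of 38 differences above 0 and a median of 0.28 (adjusted p = 0.0155, and adjusted p = 0.916 with an estimated correlation). Its members with the smallest p were krt12.2.L 0.55 ± 0.22, klf17.L 0.55 ± 0.27, grhl3.L 0.47 ± 0.23 and dlx3.S 1.24 ± 0.64 (adjusted p = 0.926 for each). That list call ended without pair 1 or 4 lacking Noggin (adjusted p = 0.943 and 0.127), pairs 1 and 2 lacking Noggin (adjusted p = 0.994) or pair 4 in Noggin (adjusted p = 0.667), and with the values as deposited (adjusted p = 0.0598) or a pseudocount of 1 (adjusted p = 0.0536).

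Noggin itself was compared between cultures that share no sibling label. In uninjected caps 1 probe set passed by limma, cnn3.L, an actin-binding calponin gene, at 441 ± 26.1 in Noggin and 177 ± 8.90 without (log2 change 1.24 ± 0.17, adjusted p = 0.0142, n = 4 arrays each), and 1275 had an unadjusted p under 0.05. The next smallest p values among higher genes were those of pim1.L, 1.73 ± 0.30 (adjusted p = 0.0891), and fzd7.L, a Wnt receptor gene, 1.09 ± 0.20 (adjusted p = 0.136). Among lower genes they were zbtb33.S -1.89 ± 0.35, eef2.1.L -0.79 ± 0.17 and paics.1.L -0.97 ± 0.21 (adjusted p = 0.133, 0.179 and 0.179). No list passed by camera: the epidermis list had a median change of -0.26, with 29 of 38 values negative (adjusted p = 0.271), and the BMP list of -0.12 (adjusted p = 0.946). The neural fate genes did not pass either, with zic1.S at 0.64 ± 0.37 and sox3.S at 0.40 ± 0.26. Of the probe sets for foxD5, foxd4l1.1.S was at 0.46 ± 0.56 and foxd4l1.2.L at 0.22 ± 0.22. Clutch, day and Noggin cannot be told apart in this comparison, and the call of cnn3.L ended without control 2 or 3 or without Noggin sample 1 or 4 (adjusted p = 0.0790, 0.0799, 0.0759 and 0.0809).

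In foxD5-injected caps 20 probe sets differed with Noggin by limma, 11 higher and 9 lower, and 1825 had an unadjusted p under 0.05. The higher genes were pim1.L, a serine/threonine kinase gene (1.90 ± 0.30), mknk2.S (1.75 ± 0.34), cdca7.L (1.51 ± 0.28), rbm7.L (1.34 ± 0.24), ctps2.L (1.29 ± 0.23), fzd7.L (1.15 ± 0.20), zfand5.L (1.12 ± 0.21) and cnn3.L (1.08 ± 0.17). The lower ones were myl9.L, a myosin light chain gene (-1.55 ± 0.21, adjusted p = 0.00974), anp32b.L (-1.41 ± 0.27), cul3.S (-1.38 ± 0.26), pdk1.S (-1.26 ± 0.18), cir1.L (-1.14 ± 0.18) and mdh1.S (-1.02 ± 0.18). Of 33 Wnt pathway genes 1 rose, fzd7.L, and 32 did not pass, with 1 higher adjusted over the list alone. The values of fzd2.S, nodal3.1.L and fzd8.S were 0.65 ± 0.19, 0.64 ± 0.28 and 0.54 ± 0.23 (adjusted p = 0.159, 0.377 and 0.381). The Wnt list was higher by camera (adjusted p = 0.0143, and adjusted p = 0.0840 with an estimated correlation), a call that ended without injected sample 4 in Noggin (adjusted p = 0.0897), without pairs 1 and 2 lacking Noggin (adjusted p = 0.146) and with the median over a gene's probe sets (adjusted p = 0.0514). All 20 probe sets had the same sign in uninjected caps, where cnn3.L alone also passed, and the effects of Noggin in the 2 kinds of caps had a correlation across all probe sets of 0.553 (Spearman's rho 0.504). These caps are siblings, and the 8 sibling pairs were also parted in the 18 ways that put 2 of each culture on each side. The correlation then had a median of 0.386 and a highest value of 0.567. Of these 18 ways 1 gave 0.553 or more, so shared siblings alone can reach such a value. Of all 34 other ways 3 did so, but some of the 34 keep part of the contrast between cultures. None of the neural fate genes passed, with changes from -0.55 ± 0.35 (gmnn.S) to 0.39 ± 0.37 (zic1.S).

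The count of 20 depended on single arrays and on settings. It was 4 without injected sample 3 lacking Noggin, 8 without injected sample 4 lacking Noggin, and 2, 4, 8 and 4 without injected sample 1, 2, 3 or 4 in Noggin. With the values as deposited it was 7, of which 42.9% were higher, against 55.0% of the 20 and 73.3% of the 15 after centring on the median. It was 0 with the 8 arrays alone, 1 with a pseudocount of 1 and 193 with 64, 107 with array weights, 96 with the probe sets of a mean above the median alone, 63 with the replicate number as a block and 62 with an intensity trend. Without pairs 1 and 2 lacking Noggin it was 18, of which 1 was higher and 17 lower.

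Whether foxD5 and Noggin, the 2 treatments of the series, changed genes alike was asked from foxD5 without Noggin and Noggin in uninjected caps, each against controls. Because both use the same 4 control arrays, the correlation across probe sets of 0.241 was set against simulated groups with no effect, which gave 0.399, and the covariance of 0.0199 against 0.0245. With the 4 pairs lacking Noggin split so that no array and no sibling was shared, the mean correlation over 6 splits was -0.080, from -0.224 to -0.00985, against -1.7e-04 ± 0.0082 (SD) in simulated groups with no effect, where genes vary independently. With siblings exchanged in the arrays themselves it ranged from -0.162 to 0.214, and 7 of 16 ways lay as far from 0 (exact p = 0.438, a test added after the data were seen). This test cannot decide the question, as 16 ways cannot give an exact p under 0.05. Exchange also carries foxD5-injected arrays into the controls of the Noggin effect, so a foxD5 effect alone shifts these values. Whether the effects of foxD5 and Noggin share a direction, oppose each other or are unrelated stays open with 4 arrays per group.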

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

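The tests of the 3 patterns weighed here were chosen after the result was seen, and the counts of other sample splits were planned. A sample was looked for that stood far from the other 3 of its group in 172 groups of values. There were 3 such samples, where 8.6 would be marked by chance at 1 in 20. The signal of foxd4l1.2.L in foxD5-injected sample 4 in Noggin was 4.82 on the normalised log2 scale against 4.13 to 4.24 in the others (gap over range 0.837). The signal of sox11.S in foxD5-injected sample 3 without Noggin was 11.48 against 11.28 to 11.31 (gap over range 0.837). The mean of the retinoic acid list in foxD5-injected sample 2 in Noggin was 5.84 against 5.61 to 5.65 (gap over range 0.848). The foxD5 effect on the epidermis list differed between the cultures in limma's camera test of the difference itself (adjusted p = 0.0155), and was less negative in Noggin. It did not pass with an estimated correlation (adjusted p = 0.916) or without pair 1 lacking Noggin (adjusted p = 0.943).

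Each count was compared with the counts from other splits of the same samples. For foxD5 over both cultures, 1 of 100 splits gave as many probe sets, the real one with 213. That is the smallest share 100 splits can give, and it takes the 8 pairs as independent, which the labels do not state. It makes chance an unlikely account of this count without excluding it. The highest other split gave 115 and differs from the real one by exchanging the siblings of pair 1 lacking Noggin alone, and 98 of the 99 others gave 0. For foxD5 without Noggin the real count was 37 and the highest of the other 7 splits 1, and for foxD5 in Noggin 49 and 0. With 8 splits a share under 0.05 cannot be reached. For Noggin in uninjected caps 1 of 35 splits gave 1 probe set or more (highest other 0), and for Noggin in injected caps 1 of 35 gave 20 or more (highest other 0). That is the smallest share 35 splits can give, and no share was adjusted over the 6 counts. Both counts were 0 with the 8 arrays of the comparison alone. Chance is therefore not firmly excluded for them, nor is a difference between clutches. For the difference of the foxD5 effects all 35 of 35 splits gave at least the real 0 (highest other 0). This decides nothing, as no split can give fewer than 0.

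The first pattern is the lower expression of epidermis and BMP genes in foxD5-injected caps. Keratin genes differed between siblings too (-0.35 ± 0.55 SD, 14 genes). Keratins are epidermis genes themselves, so a foxD5 effect on epidermis would lower them as well. The tests with keratins that follow therefore cannot tell such an effect from a difference in maturity or quality. With each array's keratin score in the fit the median change of 24 epidermis genes other than keratins went from -0.69 to -0.26 (-0.26 also in the 5 pairs left without the 3 largest keratin differences), and that of 39 BMP genes from -0.07 to -0.02. The epidermis genes still passed camera at the preset correlation (adjusted p = 0.0297 with the score and 0.0113 in the 5 pairs) but not at an estimated one (adjusted p = 0.448 and 0.640), and the BMP list did not pass (adjusted p = 0.335 and 0.454), so a difference in maturity or quality that keratins track stays open for the lists. The 11 called genes, chosen on the same pairs, went from a median of -1.28 (SD 0.28) to -0.96 (SD 0.26) with the score, where 10 passed (6 epidermis and 4 BMP genes) and smad7.L did not (-0.58 ± 0.17 SE, against -0.72 ± 0.14, adjusted p = 0.0942, its change reduced), and to -0.91 (SD 0.28) in the 5 pairs, where all 11 were lower and 7 passed (5 and 2). RNA degradation in injected caps would raise the control ratios of 3' over 5' signal together. They moved opposite ways in 6 of 8 pairs, GAPDH by 0.21 ± 0.22 and beta-actin by -0.34 ± 0.33 (SD, exact sign-flip p = 0.0391 and 0.0234). The GAPDH ratio rose in 7 of 8 pairs, as degradation would have it, and the beta-actin ratio fell in 7 of 8. These ratios therefore do not settle the question. An effect of foxD5, of injection as such and of the later stage of injected caps stay open as well.

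The second pattern is the rise of fgf8.L, foxb1.S, fgf20.L and tbxt.S, the last past the threshold in only 8 of 18 alternatives. Marginal zone tissue left on injected caps could bring mesoderm transcripts, and would raise them together. The mean of the whole list was higher by 0.15 ± 0.13 (SD), in 7 of 8 pairs (exact sign-flip adjusted p = 0.0562). That mean includes the called rises, and the median of all 38 changes was 0.035. The median change of the 13 mesoderm genes above the pseudocount was -0.057, with SD 0.80, against a smallest called rise of 0.65. The signals of fgf8.L and foxb1.S were 518 and 116 in injected caps against 143 and 21.9, while those of not.L and eomes.L were 72.8 and 29.3 against 87.8 and 41.6, but members that go both ways leave this explanation open. Injection itself rather than foxD5 stays open as well: the stress and apoptosis list differed by 0.096 ± 0.13 (SD, higher in 7 of 8 pairs, exact p = 0.0938), and no array holds another injected mRNA.

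The third pattern is the small number of probe sets that differed with Noggin. The spread between clutches is consistent with it: in fits of the same form, without the sibling block, foxD5 called 1 probe set without Noggin and 3 in Noggin, no more than the 2 and 14 of Noggin in uninjected and injected caps. At an unadjusted p under 0.05 there were 8.23% of probe sets in uninjected caps, but clutch and Noggin are confounded, so Noggin without effect on the caps and a biological effect of Noggin cannot be told apart here.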

How the results depend on the processing

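Leaving out pairs named by number together was chosen after the data were seen, and the other alternatives were planned. All 74 called values of named genes kept their direction over the planned and added alternatives. Of their 1260 values under these, 894 stayed past the threshold and 366 did not. Among the values of named genes that were not called, 116 changed sign. Counts were compared by size alone. Noggin calls in injected caps went from 11 higher and 9 lower to 1 and 17 without pairs 1 and 2 lacking Noggin. Of 181 list values, 153 stayed on their side and 28 did not. The correlation of the foxD5 and Noggin effects was from -0.135 to -0.023 under 5 alternatives, and 0 probe sets differed in foxD5 effect under all 10 alternatives and with each pair left out. Counts follow for foxD5 without Noggin (37), foxD5 in Noggin (49), both cultures (213), shared probe sets (16), Noggin in uninjected caps (1) and Noggin in injected caps (20), where they moved by over 1.5 times, and the cause was not tested except as stated. Without the sibling block they were 1, 3, 67 and 1 for foxD5, and 2 for Noggin in uninjected caps. With the pair as a random block 25 probe sets were shared. With the replicate number as a block across cultures the Noggin counts were 2 and 63. With values as deposited, 7 differed with Noggin in injected caps. With a pseudocount of 1, which spreads low signals, the counts were 0, 1, 57, 0, 0 and 1. With 64 they were 4 and 193 for Noggin. With probe sets of a mean above the median alone, 96 differed with Noggin in injected caps. With an intensity trend the counts were 92, 78 and 41 shared, and 62 with Noggin in injected caps. With array weights they were 99 in Noggin, 32 shared and 107. With the 8 arrays of a comparison alone, so fewer samples, they were 0 without Noggin, 0 shared, 0 and 0. Without pairs 1 and 2 lacking Noggin, 1, 0 shared and 0 for Noggin in uninjected caps remained, and without pairs 1 and 4 lacking Noggin and pair 2 in Noggin 94 over both cultures. Leaving out 1 pair or array gave 7 to 29, 5 to 18, 92 to 393, 3 to 18, 0 to 2 and 2 to 23. The lists past camera numbered 2, 2, 4, 1 and 1 in the 2 cultures, both, the difference and Noggin in injected caps, and 0 in each with an estimated correlation. With the median over a gene's probe sets the last was 0. Of the probe sets 28.5% had a mean signal under 16, where differences between groups were compressed.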

Other observations

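The hypotheses at the end were formed after the called genes were seen, and their tests were set before the values they measure. Other genes that differed with foxD5 over both cultures are on none of the lists and are named here after their values were seen. They were picked from the called genes and were not tested as a set. The homeobox genes lhx5.S and dlx2.L fell by 0.91 and 0.65 on the log2 scale (SE 0.14 and 0.12), and the T-box gene tbx3.S and the zinc finger genes prdm1.S and gli3.L fell by 0.94, 1.05 and 0.74 (SE 0.20, 0.16 and 0.16), each lower in 8 of 8 pairs. The ligand gene pdgfa.S (-0.91 ± 0.19) and the chemokine receptor gene cxcr4.L (-0.67 ± 0.12) were lower in 8 of 8 pairs as well. The zinc finger gene sp5l.S (1.04 ± 0.15), prickle1.L, a gene of planar cell polarity (0.90 ± 0.16), the ephrin receptor gene epha2.L (0.82 ± 0.11), the intermediate filament gene vim.L (0.76 ± 0.12) and jund.S (0.93 ± 0.11) rose in 8 of 8 pairs. The receptor gene ror2.L (1.04 ± 0.19) and the Hedgehog transducer gene smo.L (0.77 ± 0.15) rose with 7 of 8 pairs higher.

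Rises over both cultures also included the glycolysis genes hk1.L (1.37 ± 0.19), slc2a1.L (1.22 ± 0.15 in 1 probe set, 0.42 ± 0.13 and not past the threshold in the brighter one) and gapdh.L (0.67 ± 0.14). Of 40 measured genes of low oxygen response and glycolysis, 5 were called by their brightest probe set, each higher, and slc2a1.L by another. A low oxygen response in the injected caps may be proposed, and would raise the other members. The 34 members with no called probe set differed by 0.027 ± 0.12 (SD), higher in 4 of 8 pairs (exact sign-flip p = 0.680, adjusted p = 0.680). The predicted rise was thus not met, and the outcome set beforehand against the hypothesis, at most 5 of 8 pairs higher, was met. The difference lies within the spread and leaves out the called genes, so it does not exclude the hypothesis, nor does it lend it weight.

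The p53 targets ccng1.L (0.95 ± 0.21), plk2.S (0.84 ± 0.14) and sesn1.L (1.08 ± 0.12) were the called ones of 19 measured, each higher. A p53 response in the injected caps could raise them. The 16 members with no called probe set differed by -0.062 ± 0.10 (SD), higher in 2 of 8 pairs (exact sign-flip p = 0.133, adjusted p = 0.266). The outcome set beforehand against this hypothesis, a mean difference that is not positive, was met. The difference lies again within the spread, and it leaves out the called genes, all higher, which lowers it. The predicted rise of the other members was thus not met, but the hypothesis is not excluded.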
